A study of Homo sapiens with 6 samples.

How the data were processed

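RNA was sequenced from 6 samples of NCI-H441, a human lung papillary adenocarcinoma cell line, 3 infected with an empty control lentivirus (Control) and 3 with a lentivirus carrying rat Foxa2 behind a PGK promoter (FOXA2), per the labels. The labels put the time after infection at over a week. The authors deposited 1 file per sample holding whole-number read counts for 26485 gene symbols, with no summary rows. Per the submitters' processing notes, the tools were Trim Galore 0.4.2, Bowtie2 2.3.3.1, SAMtools, Picard and HTSeq with the human build hg38. The notes used here give these tools no roles and no order, and the annotation, the strand setting and the handling of duplicate reads are not given in the sources used here. Bowtie2 does not split a read across an intron, which lowers counts of genes with many short exons if the reads were aligned to the genome, in all libraries alike. Without a known strand setting, reads of overlapping and antisense genes cannot be told apart, and reads shared by close paralogs can be moved between them or lost.

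Samples were grouped by their titles. The totals ranged from 20992413 counts in FOXA2 replicate 3 to 26825148 in Control replicate 3. A gene with 0 counts in a library could hold up to 3 counts by chance, a level of 0.112 to 0.143 CPM, the count scaled to library size. Intervals and floors cover counting error only, since the reads carry no molecular identifiers. Replicates were compared by a chi-square of their counts over genes, which came to 1.76 to 5.20 per gene in each pair of libraries of a group, so that no 2 libraries differed by as little as sampling noise.

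Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr at its defaults (a count of at least 10 in enough libraries and 15 over all of them), which left 14207 of 26485 genes and removed 0.0498% of the counts. Library sizes were scaled by TMM, and group means were compared by the quasi-likelihood F test with Benjamini-Hochberg adjustment at 0.05, with the group as the sole factor. Levels are TMM-scaled CPM as mean ± SD. Standard errors of log2 fold changes were taken as the size of the fold change over the square root of F. Fitted fold changes use a prior count of 0.125 and log2 CPM values a prior count of 2. Where all libraries of a group were at 0, the fold is a lower bound from a floor of 3 counts over the group. Where a group held 1 to 3 counts, a 95% counting interval of the ratio is given from the exact binomial (Clopper-Pearson). A gene was called silent in a group when its 3 libraries held 0 counts and the other group had a mean of at least 5 CPM.

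Gene lists (27 for pathways and cell types, and 4 for markers of fibroblasts, endothelial cells, leukocytes and the HEK293 kidney line used to package lentivirus) were written before the data were examined. The 24 lists with at least 5 tested genes entered camera (limma 3.58.1) with a preset correlation of 0.01. Camera with an estimated correlation and fry, which asks whether the members of a list move on balance in 1 direction, were alternatives. The named genes follow a rule also set before the data were examined. It takes FOXA1, FOXA2 and FOXA3, the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold with a mean of at least 5 CPM in the higher group and no overlap between groups, and the 4 members of each list with the smallest adjusted p. It leaves non-coding, antisense and uncharacterised loci out of the largest changes, and allows any member of the mucin, gastric, alveolar type 2, liver and other-cell lists. Genes named outside the rule are marked as chosen after their values were seen. Older symbols were matched through RefSeq synonyms that name 1 gene. The 13 mitochondrially encoded genes were not found among the deposited gene symbols, so their list could not be tested.

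Positions came from GENCODE release 29 on GRCh38, the assembly that hg38 names, and were found for 13762 of the tested genes (96.9%). For the chromosomal analysis, genes with a log2 CPM of at least 3 were placed in bins of 10 Mb with at least 15 genes. GC content and length are those of each gene's longest transcript, and their joint trend was fitted by loess with a span of 0.5.

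The fits were tested on simulated counts for this comparison, drawn from the means, dispersions and library sizes of the 6 libraries with 200 genes changed. Over the 14062 genes that passed the filter there, the test recovered 56% of the genes changed 1.2-fold, 89.8% at 1.5-fold, 95.9% at 2-fold and 100% at 4-fold, and 7.18% of its calls were unchanged genes. These shares hold for few changed genes among many, and the adjustment is stricter there than where most genes change. A planted fall of the proliferation list was called and no other list was, and a planted chromosome-wide shift of 0.58 (log2) was recovered as 0.57. Genes were drawn independently of each other, and those outside the planted list were left unchanged. The planted fall was the same in every member, while 7 of the 38 members rose in the real data. The list result thus does not test camera where genes vary together, where members move both ways or where most genes change.

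The alternatives fixed beforehand were median-of-ratios size factors, library size alone, no filter, a mean CPM of at least 1, DESeq2 1.42.0, limma voom, the replicate number as a block, leaving out each replicate in turn, library sizes without the 50 most abundant genes, an adjusted p of 0.01 and a test against a 1.5-fold change. Those added after the data were seen were leaving out the third replicate of both groups, taking off the running median fold change of the 50 nearest genes on the chromosome, and library sizes without the 50 most abundant genes with no composition factor.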

Results

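The series asked which transcripts change when FOXA2, a forkhead transcription factor of lung, gut and liver epithelium, is expressed ectopically in NCI-H441 cells, a human lung papillary adenocarcinoma line. Poly(A) selection and other library details are not given in the sources used here. The Control group held 3 libraries of 25007267, 26349493 and 26825148 counts. The FOXA2 group held 3 libraries of 24385528, 21095081 and 20992413 counts. The labels do not say whether the replicates were separate infections, so p-values set the group difference only against the spread between these samples, which may be technical. That spread beyond counting noise, as the common coefficient of variation in edgeR, was 3.65%.

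FOXA2 transcripts rose from 0.220 ± 0.0652 CPM in Control to 19.3 ± 0.461 CPM in FOXA2 libraries (SD, n = 3 per group), a log2 fold change of 6.43 ± 0.15 (SE; edgeR adjusted p = 1.65e-15). The human gene lies on the minus strand of chromosome 20 at 22581005 to 22585455 (GRCh38) and held 17 counts in Control and 1295 in FOXA2. Because the virus carries the rat gene, these are the reads that aligned to the human one, and reads of the transgene and of the endogenous gene cannot be separated here, so the level understates or mixes both. FOXA1, the paralog that is abundant in this line, fell from 367 ± 14.3 to 317 ± 17.6 CPM (log2 fold change -0.21 ± 0.04; edgeR adjusted p = 2.72e-04). FOXA3 held 3 counts in all Control libraries together and 0 in FOXA2, too few to test.

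Of 14207 genes tested, 10106 (71.1%) changed, 5053 up and 5053 down, by edgeR's quasi-likelihood test. Most changes were small. The median size among changed genes was 0.45 on the log2 scale, and 1353 genes rose and 598 fell by at least 2-fold in fitted value. Against a 1.5-fold change, 2625 genes passed, with 1699 higher and 926 lower, so 64.7% of calls were then rises against 50% in the main test. The libraries of the groups did not overlap for 73.6% of tested genes, where chance gives 10%. The first principal component held 92.8% of the variance and separated the groups. Correlations of log2 CPM across genes were 0.995 to 0.997 within groups and 0.930 to 0.935 between them.

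**Figure D1:**
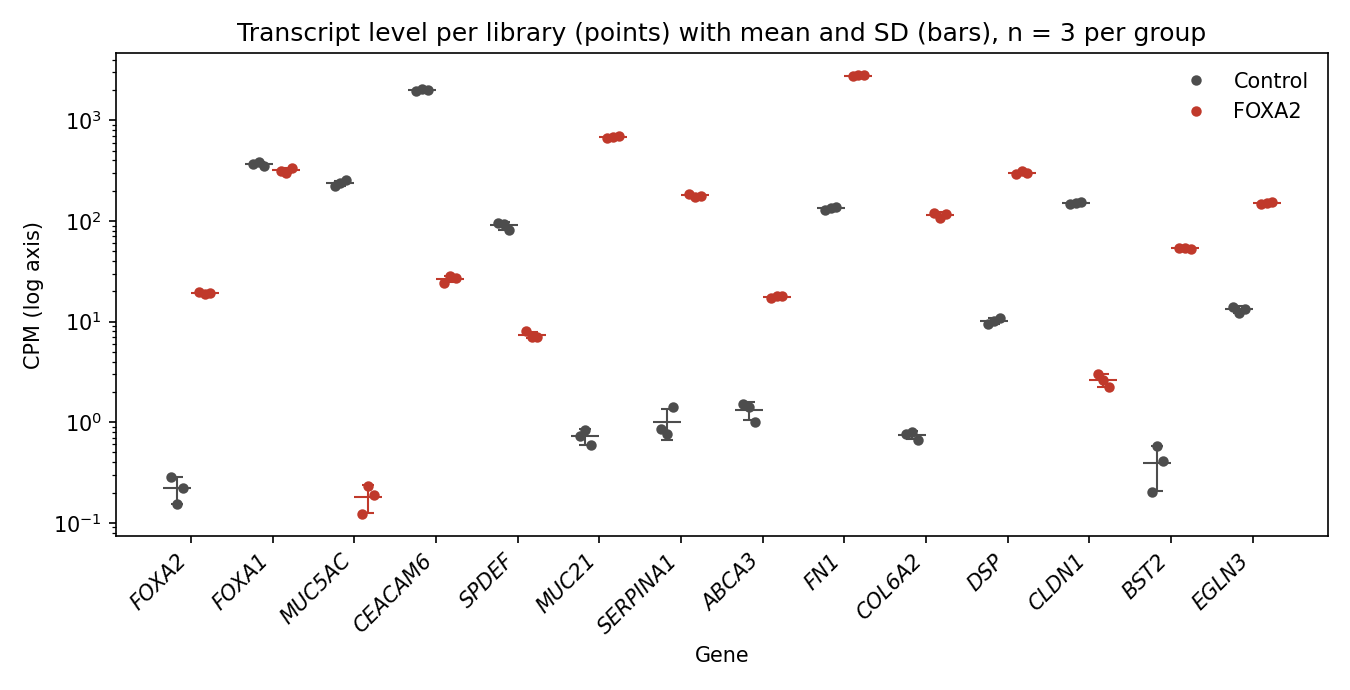
Level of 14 named genes in CPM on a log axis for each Control and FOXA2 library (points), with the mean and SD of 3 libraries per group as bars. The groups did not overlap for any gene shown, and MUC5AC went from 237 to 0.182 CPM while MUC21 went from 0.724 to 679 CPM.

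Several genes went from no detected transcript to clear expression. The zinc finger gene ZC4H2, at 0 counts in Control, reached 29.7 ± 1.82 CPM with FOXA2 and was at least 771-fold higher. The homeobox gene IRX2 and its neighbour C5orf38, which starts beside it on the opposite strand of chromosome 5, were at least 701-fold and 587-fold higher. The metallothionein MT1E was at least 588-fold higher, the sarcoglycan SGCB at least 227-fold, the tumour antigen PRAME at least 194-fold, the imprinted gene PEG3 at least 164-fold, the methyltransferase BHMT2 at least 160-fold and the glycosyltransferase GALNT14 at least 131-fold. The adhesion gene KIRREL rose from 1 count, in Control replicate 3, to 114.9 ± 0.241 CPM, a ratio with a 95% counting interval of 1598 to 351886. The bradykinin receptor BDKRB2 likewise rose from 1 count, in Control replicate 2, to 20.1 ± 1.63 CPM, with an interval of 280 to 61688. In all, 11 genes were silent in Control and expressed with FOXA2, and 2 were the reverse. MT1E has close paralogs, so its level is uncertain.

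Genes lost with FOXA2 included TOX3, an HMG-box transcriptional regulator on chromosome 16, which went from 66.0 ± 2.19 CPM to 0 counts and was at least 1474-fold lower, and the syndecan SDC2, at least 186-fold lower. The coiled-coil gene TACC1 fell from 267 to 1.82 CPM. The cell surface glycoprotein CEACAM6 fell from 1985 ± 38.6 to 26.5 ± 1.96 CPM (log2 fold change -6.23 ± 0.05; edgeR adjusted p = 2.76e-21). CEACAM5, its paralog, also fell, from 88.0 to 11.4 CPM, and reads shared between the pair could be counted for either. The calcium channel gene CACNA1H fell from 101 to 1.49 CPM, FER1L6 from 38.1 to 0.565 CPM, the adenylate cyclase gene ADCY6 from 9.40 to 0.160 CPM and KLHL35 from 6.37 to 0.117 CPM. The aldehyde dehydrogenase ALDH3A1, at 431 Control counts and 5 FOXA2 counts, had a log2 fold change of -6.12, against -5.50 without FOXA2 replicate 1 and -6.83 without FOXA2 replicate 3. That of IGFL1 was -6.79, and -7.97 without FOXA2 replicate 1.

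The mucus genes changed in opposite directions. Of 22 tested members of the mucin and goblet cell list, 8 rose and 14 fell. Over all tested genes 71.1% changed, 5053 up and 5053 down. Members that moved both ways therefore do not by themselves set this list or the later ones apart. MUC5AC, the secreted gel-forming mucin of surface goblet cells, at 1157953 to 1201138 of chromosome 11, fell from 237 ± 14.5 to 0.182 ± 0.0561 CPM (log2 fold change -10.33 ± 0.11; edgeR adjusted p = 1.39e-19). SPDEF, the transcription factor of goblet cell differentiation, fell from 90.1 ± 8.24 to 7.36 ± 0.566 CPM, and CREB3L1 from 69.5 ± 2.08 to 7.28 ± 0.530 CPM. AGR2, needed for mucin folding, MUC1 and MUC16 fell by 1.12, 1.05 and 2.24 on the log2 scale. In contrast MUC21, a transmembrane mucin, rose from 0.724 ± 0.124 to 679 ± 12.1 CPM, and MUC3A and MUC13 rose by 2.52 and 1.94 (log2). MUC2, MUC6, TFF1 and TFF3 had under 10 counts over all libraries. Of 12 tested genes of the gastric and gut list, 4 rose and 8 fell. The calpain CAPN8 fell by 0.76 on the log2 scale, while the surface antigen GPA33 rose from 1.43 to 7.37 CPM and the protease CTSE from 4 counts to 77. CDX1, CDX2, PDX1 and HNF4A had 0 counts. Camera with a preset correlation called neither list (limma adjusted p = 0.199 and 0.331), or with an estimated correlation (limma adjusted p = 0.673 and 0.722).

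Markers of alveolar type 2 cells, which make surfactant, split evenly, with 9 of 19 tested genes up and 9 down. The lipid transporter ABCA3 rose from 1.31 ± 0.264 to 17.5 ± 0.510 CPM and CXCL17 from 8.63 ± 0.586 to 48.4 ± 4.08 CPM. SFTPA2 rose from 557 to 934 CPM while its near-identical paralog SFTPA1 fell from 927 to 738 CPM, and the split between these copies depends on how shared reads were counted. The rise of SFTPA2 was 0.75 (log2), and it lies between 70 and 80 Mb of chromosome 10. There 47 of 51 binned genes were higher, with a median log2 fold change of 0.51. The phosphate transporter SLC34A2 fell from 748 ± 31.6 to 425 ± 33.2 CPM, and NKX2-1, the lung lineage transcription factor, from 603 ± 39.3 to 443 ± 23.4 CPM. SFTPC had 2 counts in Control and 0 with FOXA2. LPCAT1, a surfactant lipid enzyme, rose by 0.29 (log2), but fell by 0.15 once the shift of its chromosomal neighbours was taken off (edgeR adjusted p = 7.30e-04), an alternative chosen after seeing the data. Of 15 tested airway basal and squamous markers 7 rose and 7 fell, with TP63, the basal cell regulator, down from 32.9 ± 2.01 to 2.27 ± 0.290 CPM and KRT15 up from 13.5 to 49.3 CPM. The median and mean fold change of that list lay above 0 (0.62 and 0.70, log2) while camera's direction was down (limma adjusted p = 0.940).

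Epithelial junction genes also moved both ways, 12 of 30 up and 15 down. The desmosomal gene DSP rose from 10.2 ± 0.748 to 301 ± 8.85 CPM, while the tight junction gene CLDN1 fell from 151 ± 3.55 to 2.62 ± 0.382 CPM and JUP from 934 to 559 CPM. Of 17 tested mesenchymal genes 12 rose and 5 fell. Fibronectin, FN1, rose from 134 ± 5.08 to 2781 ± 39.7 CPM (log2 fold change 4.38 ± 0.04; edgeR adjusted p = 9.06e-21), and the collagen VI genes COL6A2 and COL6A1 rose from 0.749 to 115 CPM and from 4.15 to 55.3 CPM. Camera did not call the mesenchymal list (limma adjusted p = 0.0752, and 0.673 with an estimated correlation). It was called without the filter on low counts and with voom (adjusted p = 0.0426 and 0.0435).

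Of the 38 plasma protein and lipid transport genes of hepatocytes 7 were expressed well enough to test, and 5 rose and 2 fell. SERPINA1, alpha-1 antitrypsin, rose from 1.01 ± 0.354 to 179 ± 5.13 CPM (log2 fold change 7.45 ± 0.09; edgeR adjusted p = 2.81e-19). The acute phase genes CP and SERPINA3 rose by 1.32 and 3.59 on the log2 scale (SERPINA3 by 4.46 without Control replicate 2). The rise of VTN and the fall of APOE, both under 1 CPM, were near the threshold (edgeR adjusted p = 0.0383 and 0.0473). The call of VTN was lost without Control replicate 1, Control replicate 2, FOXA2 replicate 1 or FOXA2 replicate 2 (edgeR adjusted p from 0.110 to 0.152). That of APOE was lost without any library but Control replicate 3 (0.0541 to 0.161), and that of FGB, the other gene that fell, without FOXA2 replicate 2 (0.0626). ALB, AFP and TTR had 0 or 1 count per group. Camera did not call the list (limma adjusted p = 0.241, and 0.673 with an estimated correlation).

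Proliferation was the sole list that camera called, as lower with FOXA2. Of its 38 genes, 27 fell and 7 rose, and none changed by as much as 2-fold. The transcription factor MYBL2 fell from 256 ± 9.46 to 154 ± 5.99 CPM, the mitotic kinase PLK1 from 151 ± 2.82 to 104 ± 1.97 CPM and the replication gene MCM3 from 399 ± 13.1 to 276 ± 8.22 CPM. The call was marginal (limma adjusted p = 0.0497) and was lost with an estimated correlation (adjusted p = 0.673), median-of-ratios factors (0.0533), library size only (0.0607), a mean CPM of at least 1 (0.0869) and 2 libraries per group (0.091). It was also lost without Control replicate 3 (0.0638), without FOXA2 replicate 1 (0.0504) and without FOXA2 replicate 3 (0.0738), in adjusted p. With the shift of chromosomal neighbours taken off, an alternative chosen after seeing the data, 25 of the genes fell and 2 rose. The list was then called (limma adjusted p = 1.74e-04, with a range of 1.74e-04 to 0.673 over 16 settings). Camera was run on these shifted values with the preset correlation only, so that call decides little.

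Genes of glycolysis and hypoxia rose in 19 of 31 cases and fell in 8. The oxygen sensor EGLN3 rose from 13.2 ± 0.992 to 151 ± 3.93 CPM, NDRG1 from 362 to 1278 CPM, the kinase PDK1 from 51.9 to 121 CPM and the glucose transporter SLC2A3 from 7 counts to 393. Of 26 targets of NRF2, the regulator of antioxidant genes, 15 fell and 6 rose, among them GCLC, the rate-limiting enzyme of glutathione synthesis, from 86.2 ± 2.31 to 34.7 ± 0.766 CPM, while HMOX1 rose from 17.6 to 44.2 CPM. Camera gave limma adjusted p = 0.0752 and 0.0741 for these lists, and 0.722 and 0.673 with an estimated correlation. Both were called without the filter on low counts (0.0426 and 0.0147), with voom (0.0425 for each) and without FOXA2 replicate 2 (0.0396 and 0.0354), in adjusted p. Of 25 transcripts that follow ERK activity 16 rose and 8 fell. The phosphatase DUSP4 fell from 53.9 ± 2.48 to 4.40 ± 1.07 CPM, while the EGFR ligands AREG and EREG rose from 165 to 330 CPM and from 449 to 771 CPM (limma adjusted p = 0.199 for the list by camera, and 0.722 with an estimated correlation).

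Of 34 interferon response genes 21 rose and 11 fell. Without the third replicate of both groups 18 rose and 11 fell. With the shift of chromosomal neighbours taken off, 17 rose and 10 fell, and camera did not call the list (limma adjusted p = 0.502). Both alternatives were chosen after seeing the data. BST2, tetherin, rose from 0.396 ± 0.187 to 53.5 ± 1.10 CPM and MX2 from 0.566 ± 0.147 to 23.5 ± 1.15 CPM. Of 26 antigen presentation and checkpoint genes 16 rose and 7 fell. CD274, the checkpoint ligand PD-L1, rose from 129 ± 7.01 to 235 ± 3.55 CPM, and CD74, the class II invariant chain, from 3.18 ± 1.44 to 32.8 ± 4.43 CPM, while the peptide loading gene TAPBP fell from 353 ± 18.2 to 213 ± 6.92 CPM. Camera called neither list (limma adjusted p = 0.199 and 0.209, and 0.673 for each with an estimated correlation). Of 10 tested leukocyte markers 7 rose, and CD3E, CD14 and ITGAM did not pass the threshold. LYZ stood at 3.99 ± 3.01 and 10.4 ± 7.01 CPM, a log2 fold change of 1.34 (2.16 without Control replicate 3, and 0.67 without FOXA2 replicate 3, which ended the call, edgeR adjusted p = 0.0941). PTPRC, which encodes CD45, stood at 0.730 ± 0.310 and 1.97 ± 0.939 CPM. Without the third replicate of both groups, chosen after seeing the data, 15 antigen presentation genes rose and 7 fell. The class II genes, TAPBP and MUC21 lie between 30 and 40 Mb of chromosome 6, where 109 of 132 binned genes were lower with FOXA2 (median log2 fold change -0.36). With neighbouring shifts taken off, 19 antigen presentation genes rose and 3 fell, and camera called the list as higher (limma adjusted p = 0.0117). Taking off the shift of this block raises the members that lie in it together. Camera was run here with the preset correlation only, so the call decides little.

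**Figure D2:**
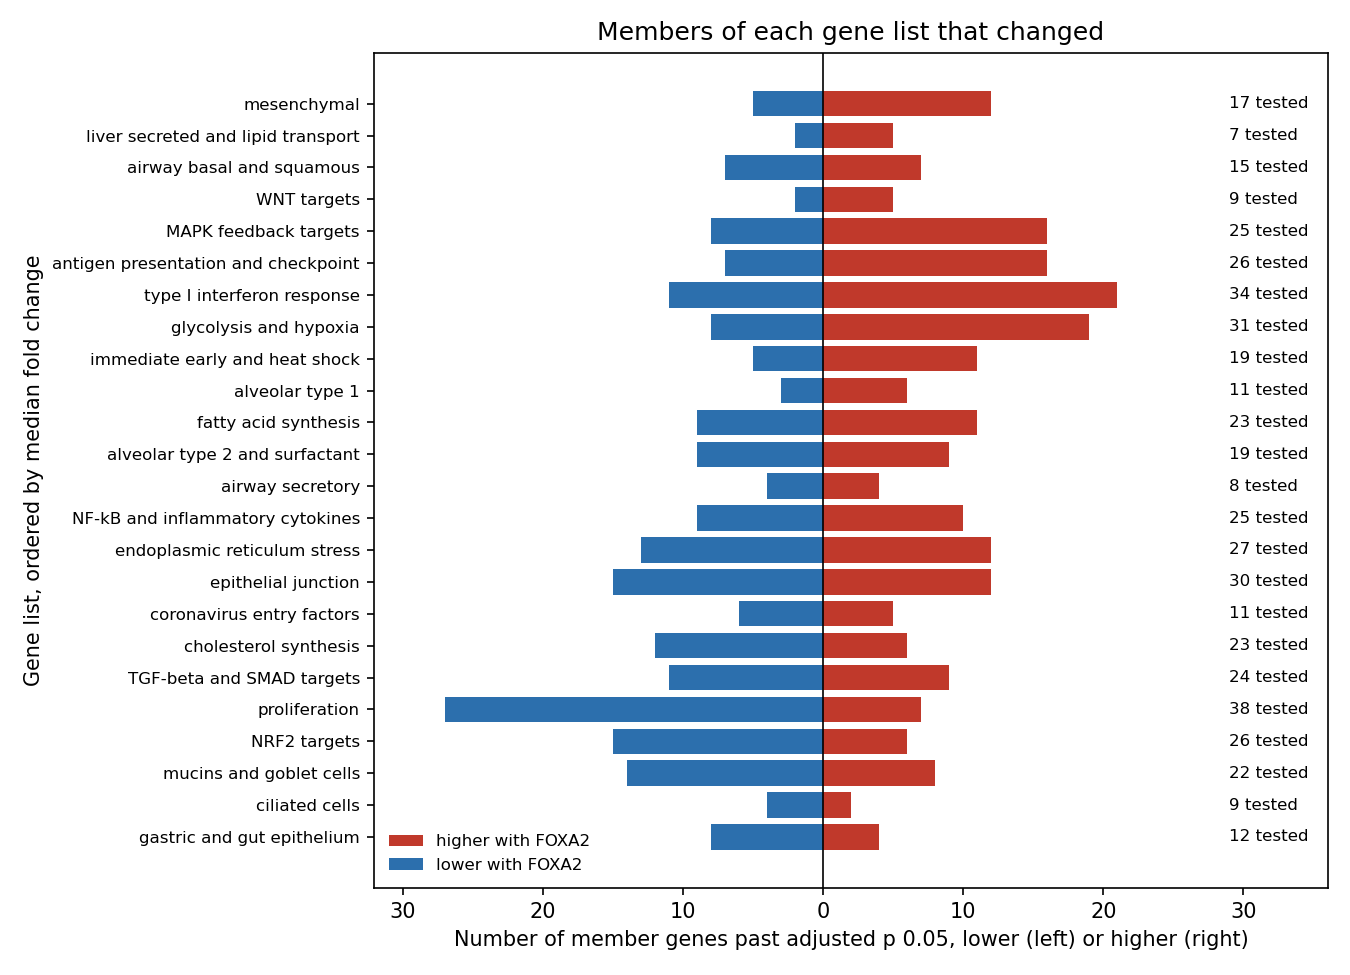
Number of member genes past the threshold in each of the 24 tested gene lists, higher with FOXA2 to the right and lower to the left, ordered by the median log2 fold change of the list. Most lists held genes of both directions, and proliferation, with 27 of 38 lower, was the sole list called by camera, a call lost with an estimated correlation (limma adjusted p = 0.673).

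Adjusted over the list alone, the counts of risen and fallen genes were the same in each list, except that 8 rather than 7 basal and squamous markers rose. Camera called 1 of 24 lists with the preset correlation and 0 with an estimated one, while 5 and 0 lists had an unadjusted p under 0.05. Fry called 13 lists as higher and 9 as lower, and all 24 as changed in either direction. It does not compare a list with other genes, and 71.1% of all tested genes changed. These calls therefore do not set the lists apart.

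Of 11 fibroblast markers only LUM and COL1A1 were tested, and both fell, LUM from 116 ± 5.38 to 29.5 ± 2.29 CPM. COL1A2, DCN and POSTN had 0 counts in all libraries. Of 10 endothelial markers 4 were tested. KDR fell from 162 ± 2.87 to 51.5 ± 3.99 CPM and CLDN5 also fell, while TEK and PECAM1 rose. Of 13 leukocyte markers 10 were tested and 7 rose, of which CD68 was the most abundant at 97.4 and 204 CPM. The 10 markers of the HEK293 line, used to package lentivirus, summed to 2 to 11 counts per library.

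Fold changes ran in blocks along the chromosomes. Among 242 bins of 10 Mb, 34 had a median log2 fold change of at least 0.3 in size, 22 higher and 12 lower. All 41 binned genes between 100 and 110 Mb of chromosome 14 were lower (median -0.74), and all 37 between 110 and 120 Mb of chromosome 10 were higher (median 0.65). SERPINA1 and BDKRB2, which rose, lie between 90 and 100 Mb of chromosome 14, where the median was -0.56, and IRX2 and C5orf38 lie in the first 10 Mb of chromosome 5, where it was 0.44. With the running median of the neighbours taken off, an alternative chosen after seeing the data, 9470 genes changed, 8287 of them among the original 10106, and 256 of these had the opposite sign.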

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

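The alternatives that leave out the third replicate of both groups, take off the chromosomal shift, or drop the 50 most abundant genes together with the composition factor were chosen after seeing the data. The 10106 changed genes, 5053 higher and 5053 lower, numbered 9300 to 10807 changed over the other tools, scalings, filters and offsets at an adjusted p of 0.05, with none of the shared calls of opposite sign except 256 under the chromosomal offset. The even split shifted to 5306 higher and 4746 lower with library size only (52.8% higher) and to 5215 higher and 4255 lower with the chromosomal offset (55.1%). At an adjusted p of 0.01, 8783 genes changed. The test against a 1.5-fold change gave 2625 genes changed, 1699 higher and 926 lower, because it asks for more than a difference. Leaving out each replicate in turn gave 9554 to 10132 genes changed, 4802 to 5083 higher and 4684 to 5049 lower. Removing the 50 most abundant genes from the library sizes moved nothing, since TMM cancels it, and says nothing on stability; with no composition factor it gave 10069 genes changed, and library size alone 10052.

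Gene lists called depended on the setting. Camera called 1 list in the main setting, 0 with median-of-ratios factors, 0 with library size only, 0 with a mean CPM of at least 1, 0 with library sizes without the 50 most abundant genes and no composition factor, 0 with 2 libraries per group, 0 with an estimated correlation, 4 without the filter, 4 with voom and 2 with the chromosomal offset; fry called 22, since it does not compare a list with other genes. Leaving out each replicate gave 0 to 3 lists. Proliferation kept its direction under the 16 camera settings that moved something, the estimated correlation included, and was called in 7 and not in 9, with adjusted p from 1.74e-04 to 0.673. Apart from the wider question asked by fry, the cause was not tested.

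Of 182 named genes tested, 174 to 182 kept direction and call under each alternative counted here (168 of the 169 left by the stricter filter). The stricter adjusted p and the test against a minimum fold change were not counted for the named genes. Over all genes they ended 1323 and 7481 of the main calls. Under at least 1 of the alternatives counted, the calls of APOE, VTN, VSIG1, FCER1G, PIGR, FGB, LYZ, KLF4, DNAH5 and BSG were lost. CD3E, CD14 and ITGAM became calls. LPCAT1 was reversed by the chromosomal offset, to -0.15, because its neighbours on chromosome 5 were higher with FOXA2.

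The replicate numbers were not taken to pair the samples, since the deviations of same-numbered libraries correlated at 0.17, -0.02 and 0.19, not all over 0.1. As a hint from the data that goes the other way, replicates 1 and 3 of both groups correlated best with their own number, and the second principal component (2.57% of the variance) ordered the replicates alike in both groups (10.4, 3.66 and -14.8 in Control, 10.3, 1.88 and -11.5 in FOXA2). With the replicate block, 10185 genes changed, 5091 higher and 5094 lower, of which 10014 were shared, and 1 list was called. Among the named genes, the block ended the calls of APOE and VTN (adjusted p = 0.0519 and 0.0520) and made calls of CD3E and CD14. At this depth a transcript at 0 counts in a library could still stand at up to 0.112 to 0.143 CPM.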

Other observations

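The tests of other splits, of chance positions and of ratios between libraries were chosen only after the result was seen. Lists of lipid and stress genes held further changes in both directions. Of 23 fatty acid synthesis genes 11 rose and 9 fell, and the triglyceride enzyme DGAT2 rose from 0.479 ± 0.0609 to 25.7 ± 0.338 CPM and the elongase ELOVL6 from 19.6 to 101 CPM (n = 3 per group). Of 23 cholesterol genes 6 rose and 12 fell, with HMGCS1 up from 245 to 486 CPM. Of 27 endoplasmic reticulum stress genes 12 rose and 13 fell, ASNS up from 143 to 278 CPM and HYOU1 down from 544 to 326 CPM; the median was -0.03, the mean 0.13. Of 19 immediate early and heat shock genes 11 rose and 5 fell, JUN from 92.4 to 191 CPM. Camera called none of these lists (limma adjusted p = 0.658, 0.266, 0.901 and 0.199). With the shift of chromosomal neighbours taken off, 2 rather than 5 of the immediate early genes fell, and without the third replicate of both groups 3 rather than 6 cholesterol genes rose.

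Among lineage lists, 6 of 11 alveolar type 1 genes rose and 3 fell (AQP4 from 1.46 to 9.34 CPM), 4 of 8 airway secretory genes rose and 4 fell (WFDC2 from 5.99 to 29.7 CPM, TSPAN1 from 102 to 41.9 CPM), 2 of 9 ciliated cell genes rose and 4 fell, and 3 of 4 neuroendocrine genes rose (SCG5 from 3.22 to 8.94 CPM). Of 24 TGF-beta targets 9 rose and 11 fell (ID1 from 278 to 117 CPM), of 25 inflammatory genes 10 rose and 9 fell (IL18 from 8.86 to 0.441 CPM), and of 9 WNT targets 5 rose and 2 fell (SOX9 from 1.19 ± 0.131 to 23.7 ± 1.02 CPM). Of 11 coronavirus entry genes 5 rose and 6 fell, 3 with the neighbours' shift taken off (DPP4 up by 2.05, log2). Camera called none of these 7 lists that were large enough to test (limma adjusted p from 0.322 to 0.901). The median and camera's direction differed in sign for the airway secretory list (0.02, down), the inflammatory list (0.02, down) and the coronavirus list (-0.12, up).

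The real grouping gave 10106 changed genes by edgeR, and the highest of the other splits of the 6 libraries gave 0, with 15 to 125 genes at an unadjusted p under 0.05. It was the 1 split of 10 with as many changed genes, and 10 splits are too few for a share under 0.05. Every other split mixes libraries of both groups, so the group difference widens its spread. Its 0 calls therefore do not bear on whether the real count arose by chance.

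Fold changes in blocks along the chromosomes were seen in all libraries of a group: bin values correlated at 0.881 or more between libraries of a group. The SD of the bin medians was 0.208, above the highest of 1000 shuffles of gene positions (0.104), and stayed at 0.201 after removing the trend on GC content and transcript length (highest shuffle 0.0984), which argues against chance positions and against GC content and length. A candidate explanation is a copy number difference between the cultures, which would shift weakly and strongly expressed genes alike. Bin medians of the genes of lower and of higher expression correlated at 0.828 over 198 bins (highest shuffle 0.227), consistent with it. On chromosome 10 the bin medians were -0.12 to 0.05 from 0 to 40 Mb and 0.36 to 0.65 from 40 to 130 Mb. On chromosome 5 they were 0.44 and 0.39 at 0 to 10 and 30 to 40 Mb, and -0.10 to 0.20 further along. Those of chromosome 2 ran from 0.04 to 0.38 with no such step. Long runs with a step between them are what a copy number difference of chromosome parts would give. They do not exclude regional regulation by FOXA2, since no DNA was analysed here. Whether a group's 3 libraries came from a single infected culture also stays open.

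Leukocyte transcripts were highest in replicate 3 of each group for 9 of the 12 first-list genes with enough counts in both groups, and LYZ, the most abundant of those under a mean of 5 CPM in Control, was at 18.3 CPM in FOXA2 replicate 3. Of 29 genes of a second leukocyte list, 14 (0.483) were highest in the same libraries, as RNA of blood leukocytes would give. Chance gives 11.1% if genes peak in libraries independently. The third replicates stood apart alike in both groups on the second principal component (-14.8 and -11.5), and the share over all genes was not computed. The excess over 11.1% therefore cannot be credited to leukocyte RNA. Of the 18 tested genes of the second list 9 rose and 7 fell. Of those that fell, 6 belong to the 9 with at least 5 CPM in Control, like CD68 of the first list, which may be expressed by the line. Among these 6 were CLEC7A, down by 2.27, and CORO1A, down by 1.21 (log2), both chosen after their values were seen. Between FOXA2 replicates 3 and 1 the 12 first-list genes other than CD68 differed 2.82-fold (95% counting interval 2.50 to 3.20; 2.36 and 2.03 to 2.76 without LYZ), the 23 second-list genes under 5 CPM in Control 1.82-fold (1.56 to 2.12), and the first list with CD68, which held most of its counts, 1.09-fold (1.04 to 1.13). CD74 and HLA-DMA together differed 1.18-fold (1.08 to 1.29), with CD74 alone at 1.31 (1.18 to 1.46) and HLA-DMA alone at 0.873 (0.73 to 1.04). These intervals lay below those of the leukocyte genes without CD68. The pair, and HLA-DMA as a named gene, were chosen after these values were seen. The difference therefore cannot decide whether leukocyte RNA was the source of their rise. The median log2 fold change of all 5 class II and CD74 genes (1.72) lay only 0.39 SD above that of the leukocyte genes. HLA-DRA, HLA-DPA1 and HLA-DMB, a set formed after its values were seen, differed 2.39-fold (1.83 to 3.16), but HLA-DPA1 alone 1.76-fold (0.898 to 3.55). Leukocyte RNA as the source of the rise of all 5 genes stays open, and how such RNA could have entered the libraries was not tested.

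Of the 13 genes silent in a single group, 5 had a neighbour within 100 kb expressed in the other group, and 4 of these 8 neighbours (0.5) kept a CPM of at least 1 in the silent group, too few to judge a loss of the surrounding DNA. IRX2 and C5orf38, silent in Control and under 1 kb apart, are each other's neighbours in this count; without that pair the share was 4 of 6 neighbours of 3 genes (0.667). Next to SDC2, CPQ fell from 5.54 to 0.149 CPM, and next to BHMT2, DMGDH rose from 0.0128 to 1.25 CPM, both chosen after their values were seen. FOXA2-driven regulation and divergence of the cultures stay open, as untested.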
